A study of Homo sapiens with 12 samples.

How the data were processed

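Poly(A)-selected RNA was sequenced from 12 samples of 2 human prostate cancer cell lines, in 4 groups taken from the sample titles. The first experiment used cultured C4-2 cells carrying an inducible FAM3B construct (2 libraries) or serving as controls (2 libraries). Both C4-2 groups received doxycycline at 200 ng/ml for 48 hours. The second experiment used VCaP cells, titled VCaP-CR in the series and called VCaP here, with a control shRNA (4 libraries) or a FAM3B shRNA (4 libraries), grown as subcutaneous tumours in castrated SCID mice and labelled as 3 weeks of androgen deprivation. Per the labels' protocols, the C4-2 libraries were unstranded and the VCaP libraries stranded, and different providers and platforms sequenced the 2 experiments. Line, growth condition and sequencing are therefore confounded with each other, and each experiment was compared within itself.

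The authors deposited a gene table for each sample, without pooling. Per the file headers, each table holds RSEM expected counts, TPM, FPKM and effective lengths for 58026 genes. The deposited expected counts are estimates and can be fractional, because RSEM shares reads between transcripts and between similar genes. Of the nonzero values, a median of 39.5% per library in C4-2 and 38.9% in VCaP were not whole (tolerance 0.005). The deposited TPM values are scaled by effective length within each library; the deposited FPKM values were not used. Per the submitters' processing notes, Bowtie and RSEM were used with the GRCh38 (hg38) genome. Versions, the annotation release, the strand setting of the counting and any removal of mouse reads from the tumour libraries are not given in the sources used here.

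The main test was edgeR's quasi-likelihood test on the expected counts rounded to whole numbers, with TMM factors and the filterByExpr filter, fitted separately in each experiment. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. CPM values were computed here from the counts and TMM-scaled library sizes. Fold changes are FAM3B-expressing minus control in C4-2, and FAM3B-shRNA minus control-shRNA in VCaP. Gene lists were tested with limma's camera on edgeR log-CPM (prior count 2, preset correlation 0.01), adjusted over all lists with at least 5 tested members. There were 42 lists, written from general knowledge before the data were examined, covering androgen signalling, growth, metabolism, stress, lineage, other cell types and RNA quality; 1152 of their 1157 symbols were found. The difference between the lines was the contrast of the C4-2 effect minus the VCaP effect, both oriented as more FAM3B minus less FAM3B, in a single edgeR fit of all 12 libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Coordinates, biotypes and GC content come from GENCODE release 29 on GRCh38, in which 55371 rows (95.4%) matched by transcript. Gene symbols are those of the deposited tables.

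Named genes followed a rule fixed before the data were examined: FAM3B and 1 gene that, with the results that depend on it, is not reported here; the 8 largest rises and the 8 largest falls among called genes with a mean CPM of at least 1, non-overlapping groups and a symbol that is not a clone, antisense or pseudogene name; and up to 3 members of each list with the smallest p-values. Genes called in both experiments would also have been named, but there were 0 (edgeR). For lists that are not described, values are left out for length. Chosen after their values were seen were, in C4-2, KLK2, KLK3, FKBP5, CDK6, MYL12A and MKI67, and in VCaP, KLK3, EGFR, CACNA1B, BSN, LIMS1, CECR6 and SOGA3.

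The total expected count per library ran from 17343868 to 18117886 in C4-2 and from 25166242 to 27281892 in VCaP. The biological coefficient of variation was 11.9% in C4-2 and 18.5% in VCaP. The procedure was tested on simulated data drawn as negative binomial counts from the fitted means, dispersions and library sizes. Each gene was drawn independently, without a length trend, and changes were placed only in genes above a minimum abundance. In the C4-2 simulation (15152 genes) it recovered 25.4% of 1.5-fold, 76.1% of 2-fold and 93.9% of 4-fold changes, and 4.41% of its calls were false. In the VCaP simulation (15596 genes) it recovered 26.9%, 83.6% and 100% of the same fold sizes, and 6.67% of its calls were false. Every pair of replicates differed beyond sampling noise (chi-square per degree of freedom 4.37 to 69.0), so no library was counted as a duplicate. Nothing states whether replicates came from separate cultures or separate mice, so p-values measure only the spread between these samples.

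Alternatives were RLE, upper-quartile or no composition factors, DESeq2, limma-voom, no filter, a stricter filter, the replicate number as a block, leaving out each library, a single fit of 12 libraries, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), an estimated correlation, fry and a protein-coding background. Corrections for gene length and GC content, as smooth trends per library entered as offsets, were added after seeing the data. Gene length here is the deposited transcript length per gene, averaged over libraries. Also added then was a comparison of the ribosomal list with 10000 random lists, each gene drawn from the 50 nearest in length and abundance.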

Results

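The series profiled poly(A) RNA from prostate cancer cells in which FAM3B, a secreted cytokine-like protein, was raised or lowered. C4-2 is a castration-resistant derivative of the LNCaP prostate cancer line, and VCaP is a prostate cancer line with a TMPRSS2-ERG fusion. There were 2 control and 2 FAM3B-inducible C4-2 libraries, and 4 control-shRNA (shControl) and 4 FAM3B-shRNA (shFAM3B) VCaP tumour libraries, titled VCaP-CR. The total per library ran from 17343868 to 18117886 expected counts in C4-2 and from 25166242 to 27281892 in VCaP.

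The C4-2 comparison asked what inducing FAM3B did to the transcriptome. FAM3B transcripts (ENSG00000183844; chromosome 21, 41304212 to 41357431, GRCh38, a protein-coding gene) rose from 1.07 ± 0.23 CPM (SD, n = 2) in controls to 36.4 ± 14.8 CPM (SD, n = 2), 33.9-fold (log2 fold change 5.08, SE 0.34, edgeR adjusted p = 0.000823). Controls held 0.910 and 1.23 CPM (17 and 22 counts) and inducible cells 25.9 and 46.9 CPM (434 and 831 counts). Genes that androgen induces were lower as a list, and genes of the ribosome and the respiratory chain were higher (limma camera). With an estimated correlation each of these lists had an adjusted p = 0.86, and 0 lists passed. That correlation was estimated from 2 libraries per group, and even ribosomal genes, 49 of 49 with a positive fold change, did not pass. Not passing there leaves these lists unsettled and does not show them unchanged.

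**Figure D1:**
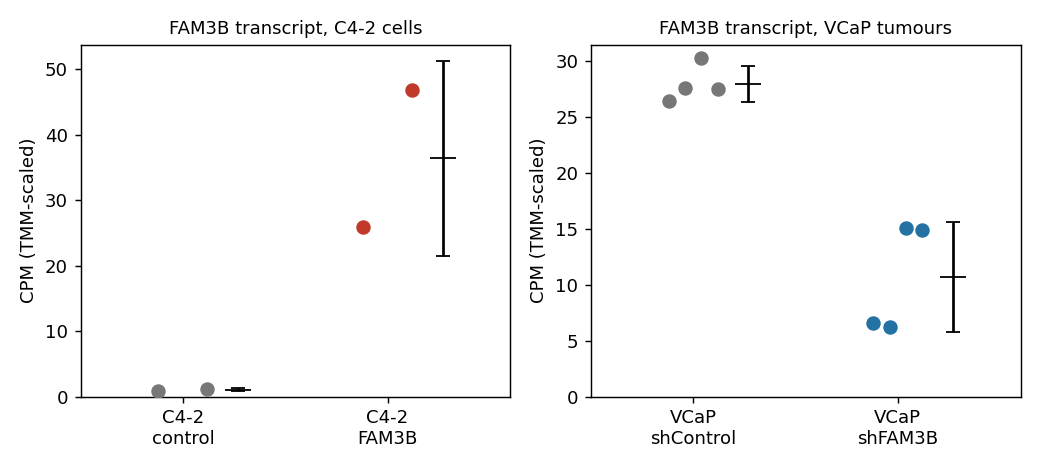
TMM-scaled CPM of FAM3B in each library (dots), with group means and SD (black bars), for C4-2 cells (n = 2 per group) and VCaP tumours (n = 4 per group). FAM3B was at 25.9 and 46.9 CPM in the inducible C4-2 libraries, and its VCaP groups did not overlap.

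Of 15439 genes tested in C4-2, 327 rose and 259 fell with FAM3B (edgeR), 55 and 78 of them by at least 2-fold. Beside FAM3B, the largest rises among genes named by rule were CXCR5, a B-cell chemokine receptor (log2 fold change 3.05, SE 0.51), and CBLN2, a synapse organiser (2.71, SE 0.27). Others were RALYL, an RNA-binding protein (2.60, SE 0.41), CAMK2N1, an inhibitor of calmodulin kinase II (2.21, SE 0.18), and HBM, a globin chain (2.04, SE 0.48). The largest falls included BRINP1, a neural cell cycle inhibitor (-2.95, SE 0.43), and PDE4B, a cyclic AMP phosphodiesterase (-2.74, SE 0.59). With them were CYP3A5, a drug and steroid oxidase (-2.02, SE 0.44), and ADRA2A, an adrenergic receptor (-1.63, SE 0.33). After removal of the length trend HBM (1.67, SE 0.49), PDE4B (-2.60, SE 0.59), CYP3A5 (-2.03, SE 0.45) and ADRA2A (-1.46, SE 0.34) missed the threshold (edgeR adjusted p from 0.0521 to 0.112), and all 4 missed it without control replicate 1. DESeq2 gave CXCR5 an adjusted p = 0.0789 and gave HBM, PDE4B and CYP3A5 none. Most of these were scarce: CXCR5 went from 1.61 ± 1.73 to 13.5 ± 0.86 CPM and PDE4B from 1.77 ± 0.37 to 0.257 ± 0.195 CPM (SD, n = 2 each). HCG25 (2.14), BLOC1S5-TXNDC5 (1.98), RGPD5 (-3.96), BIVM-ERCC5 (-3.08), SNORD109A (-2.20) and ZBED6 (-1.84) also passed. They overlap, read through into or closely resemble other genes in unstranded libraries, so their values are uncertain, and RGPD5 varied between the controls (19.5 ± 18.8 CPM, SD, n = 2). BIVM-ERCC5 (edgeR adjusted p = 0.0565) and SNORD109A (0.0502) missed the threshold with the length trend removed. The counts rest on few libraries: calls numbered 73 higher and 65 lower without control replicate 1, and 76 and 80 without control replicate 2. They numbered 1863 and 1711 without FAM3B replicate 1, and 2658 and 2619 without FAM3B replicate 2. Scaling by library size alone gave 192 higher and 498 lower (27.8% higher against 55.8%), and limma-trend on log2(TPM + 1), which put the median of all genes at -0.20, called 4 higher and 0 lower. Of 50 called C4-2 genes followed over the settings, 12 stayed called without control replicate 1, 16 without control replicate 2, 24 with the length trend removed, 6 in a single fit of 12 libraries and 1, FAM3B, on log2(TPM + 1).

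Canonical androgen-induced genes were lower with FAM3B. Of 29 tested, 6 fell, 23 did not pass and 25 had a negative fold change; adjusted over the list alone, 14 fell and 1 was higher. The list's median log2 fold change was -0.36 (limma camera adjusted p = 2.7e-05; adjusted p = 0.86 with an estimated correlation). The 6 included SLC45A3, a prostate membrane transporter (349 ± 29.7 to 198 ± 1.13 CPM, -0.82), CHRNA2, a nicotinic receptor subunit (-0.86), and HERC3, a ubiquitin ligase (-0.76). With them were TMPRSS2, a serine protease (-0.53), FKBP5, a co-chaperone (-0.54), and PMEPA1, which dampens TGF-beta signalling (-0.53). The kallikreins KLK3, which encodes prostate-specific antigen, and KLK2 had values of -0.16 (edgeR adjusted p = 0.351) and -0.10 (edgeR adjusted p = 0.641). Leaving out control replicate 1 ended all 6 calls with folds from -0.84 to -0.46, among them SLC45A3 at -0.73 (edgeR adjusted p = 0.169), TMPRSS2 at -0.51 (0.574) and FKBP5 at -0.49 (0.581). Leaving out control replicate 2 ended 5, all but SLC45A3, with TMPRSS2 at -0.55 (0.402) and FKBP5 at -0.59 (0.295). The folds stayed close while the SE of TMPRSS2 went from 0.11 to 0.25 in both. FKBP5 also lost its call with the length trend removed, going from -0.54 (SE 0.12) to -0.37 (SE 0.085; edgeR adjusted p = 0.0577), and the other 5 passed.

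The wider androgen response list moved less. Of 100 members, 7 fell, among them ABHD2, a progesterone-dependent lipid hydrolase (-0.73), ADAMTS1, a matrix protease (-0.65), and CDK6, a cell cycle kinase (-0.93); MYL12A, a myosin light chain, rose (0.56). Without control replicate 1 or 2 these 4 genes missed the threshold. CDK6 went from -0.93 (SE 0.18) to -0.57 (SE 0.17; edgeR adjusted p = 0.112) and MYL12A from 0.56 (SE 0.11) to 0.29 (SE 0.11; edgeR adjusted p = 0.200) with the length trend removed, and ABHD2 passed at -0.42. Adjusted over the list alone, 15 fell and 1 rose. The list's median was -0.21 (limma camera adjusted p = 0.00319; adjusted p = 0.86 with an estimated correlation), with 71 members below 0. The call ended without control replicate 1 (-0.17, adjusted p = 0.051), without FAM3B replicate 1 (-0.16, adjusted p = 0.149) and with the length correction (-0.049, adjusted p = 0.0693).

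**Figure D2:**
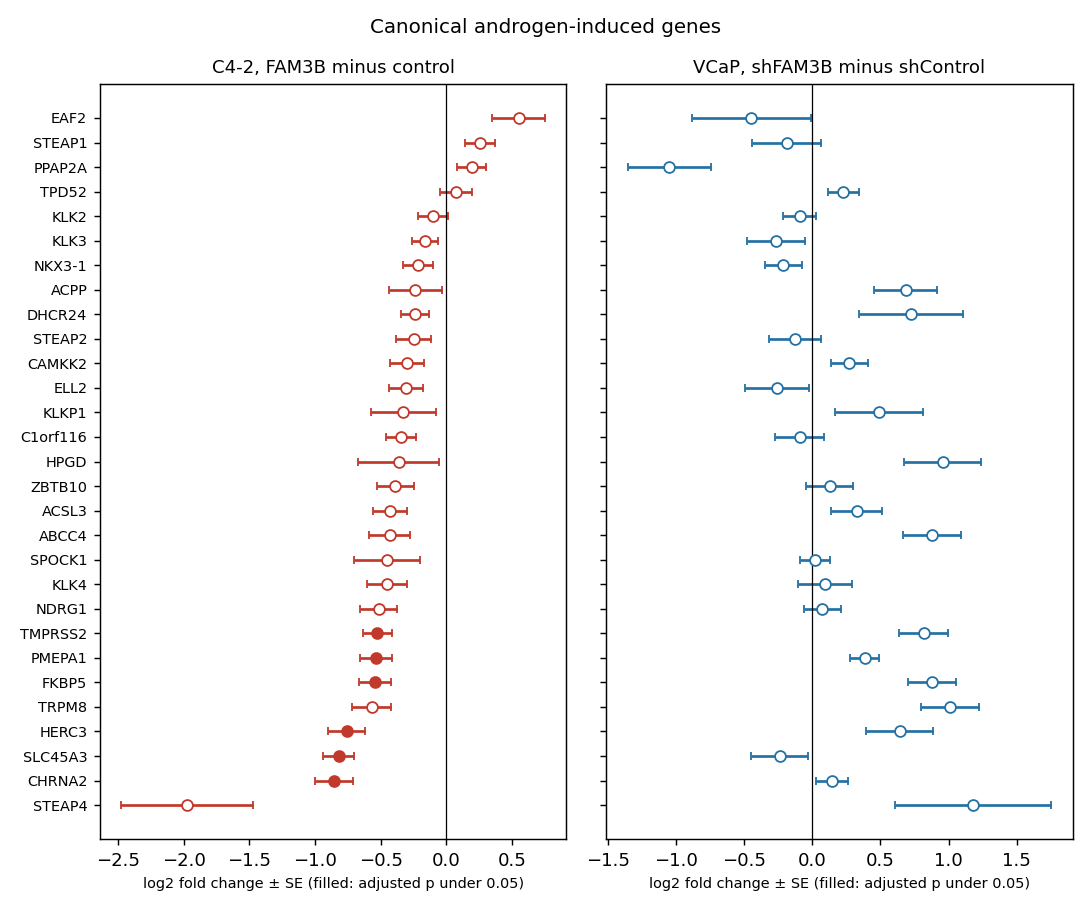
Log2 fold change (x axis, bars are SE) of each canonical androgen-induced gene, in C4-2 (FAM3B minus control, n = 2 per group) and VCaP (shFAM3B minus shControl, n = 4 per group); filled points have an edgeR adjusted p under 0.05. In C4-2, 25 of 29 genes lie below 0 and 6 are filled; in VCaP, 19 of 29 lie above 0 and 0 are filled.

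Ribosomal protein genes were higher with FAM3B: 23 of 49 rose, 26 did not pass and 49 had a positive fold change; adjusted over the list alone, 45 rose. Their median was 0.53 (limma camera adjusted p = 1.7e-14; adjusted p = 0.86 with an estimated correlation), with RPS20 at 0.73, RPL5 at 0.70 and RPS19 at 0.70. The median was 0.69 in FAM3B replicate 1 and 0.35 in FAM3B replicate 2, relative to the controls. Of 51 nuclear genes of the respiratory chain, 8 rose (26 adjusted over the list alone), including the ATP synthase subunit ATP5O (0.73), the complex I subunit NDUFB5 (0.63) and the complex III subunit UQCRFS1 (0.55); their median was 0.36 (limma camera adjusted p = 7.2e-08; adjusted p = 0.86 with an estimated correlation). The respiratory chain median was 0.19 without FAM3B replicate 1 and 0.53 without FAM3B replicate 2. On log2(TPM + 1) it was 0.093, and the ribosomal median 0.25. Fold changes followed gene length in the same libraries: of 10 bins by length, the shortest had a median of 0.37 and the longest -0.30, and the genes that rose and fell had median lengths of 974 and 4184 bases. With the length trend removed, the ribosomal median was 0.18 (camera adjusted p = 9.2e-06) and the respiratory chain median 0.095 (camera adjusted p = 0.0693). Of the 6 genes named, RPL5 (0.44) and UQCRFS1 (0.69) then passed. RPS20 (0.38), RPS19 (0.33), ATP5O (0.44) and NDUFB5 (0.37) did not (edgeR adjusted p from 0.0599 to 0.104; SE 0.088 to 0.10, against 0.11 to 0.13 before). Without control replicate 1 or 2, 0 of the 6 passed.

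Cell division genes were modestly higher. Of 42 DNA replication genes, 3 rose (6 adjusted over the list alone): the clamp loader subunits RFC4 (0.58) and RFC2 (0.54) and the sliding clamp PCNA (0.47); their median was 0.16 (limma camera adjusted p = 0.00865; adjusted p = 0.86 with an estimated correlation). Of 50 mitosis genes, 3 rose: the securin PTTG1 (0.85), the kinetochore component NDC80 (0.53) and the kinase cofactor CKS1B (0.59). The proliferation antigen MKI67 fell (-0.50); adjusted over the list alone, 8 rose and 1 fell, with a median of 0.20 (limma camera adjusted p = 0.00319; adjusted p = 0.86 with an estimated correlation). Of 20 chaperone genes, CACYBP (0.54) and HSPA8 (0.41) rose, the same 2 adjusted over the list alone, with a median of 0.23 (limma camera adjusted p = 0.00894; adjusted p = 0.86 with an estimated correlation). The list medians with the length trend removed were 0.16 for replication (camera adjusted p = 0.000819), 0.19 for mitosis (adjusted p = 7.3e-05) and 0.22 for chaperones (adjusted p = 0.0200). Of single genes PTTG1 (0.51) and NDC80 (0.50) then passed. RFC4 (0.36), RFC2 (0.38), PCNA (0.29), CKS1B (0.27), CACYBP (0.29), HSPA8 (0.25) and MKI67 (-0.13) did not (edgeR adjusted p from 0.0955 to 0.505; SE 0.070 to 0.11, against 0.093 to 0.14 before). Without control replicate 1 or 2, 0 of these 9 genes passed. On log2(TPM + 1), which put the median of all genes at -0.20, the list medians were -0.082, -0.034 and -0.029 and HSPA8 was at -0.10, all above that median. Mitosis passed there (camera adjusted p = 0.0494), and replication and chaperones did not (adjusted p = 0.238 each). Leaving out control replicate 1 ended all 3 calls (replication 0.15, adjusted p = 0.176; mitosis 0.14, adjusted p = 0.176; chaperones 0.19, adjusted p = 0.0627), FAM3B replicate 2 that of mitosis (0.12, adjusted p = 0.172) and FAM3B replicate 1 that of the chaperones (0.22, adjusted p = 0.117). In a single fit of 12 libraries the chaperones were at 0.24 (adjusted p = 0.224).

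**Figure D3:**
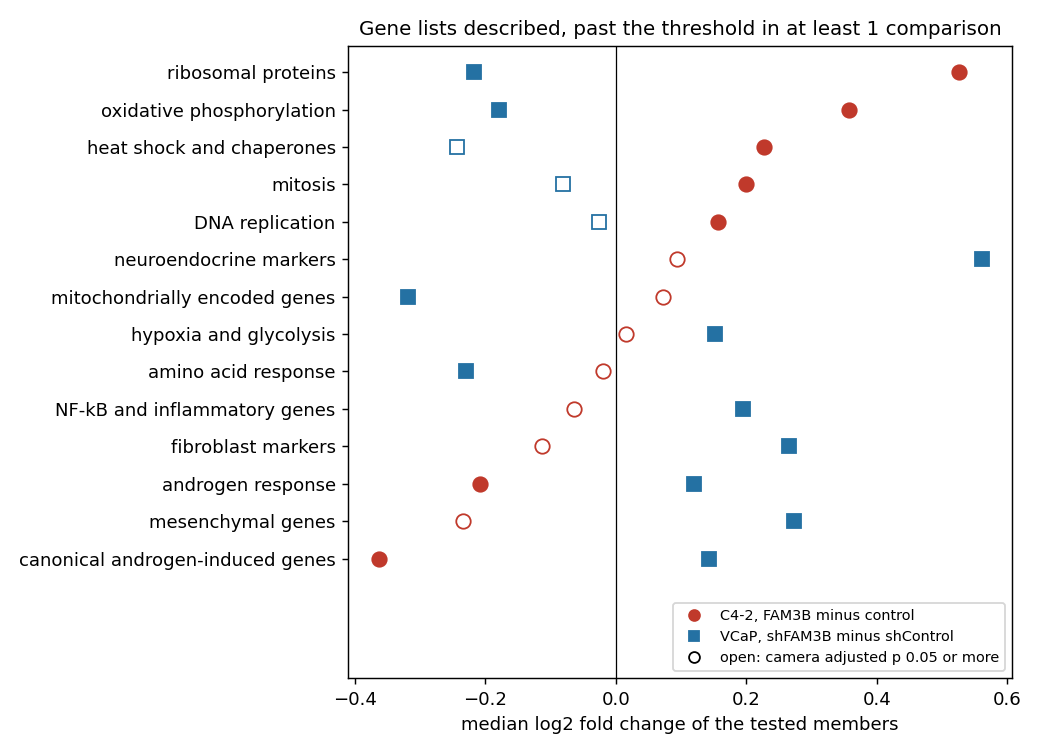
Median log2 fold change (x axis) of the tested members of each gene list described that passed the threshold in at least 1 comparison, for C4-2 (circles, n = 2 per group) and VCaP (squares, n = 4 per group); open symbols have a camera adjusted p of 0.05 or more. Ribosomal proteins were at 0.53 in C4-2 and -0.22 in VCaP.

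Among the C4-2 lists that did not pass, single genes did. FN1, fibronectin, went from 1650 ± 72.4 to 831 ± 142 CPM (SD, n = 2 each; log2 fold change -0.99, SE 0.13, edgeR adjusted p = 0.0115), in a mesenchymal list with a median of -0.23 (camera adjusted p = 0.154). On log2(TPM + 1), with the median of all genes at -0.20, FN1 was at -0.48 (limma-trend adjusted p = 0.0912). The lipogenic enzymes FASN (-0.65) and ACACA (-0.53) fell, in a fatty acid list with a median of -0.20 (camera adjusted p = 0.176), and so did the growth factor receptor IGF1R (-0.67). These 3 calls ended without control replicate 1 or 2, in a single fit of 12 libraries and on log2(TPM + 1), where FASN was at -0.070 (limma-trend adjusted p = 0.667). Removing the length trend left FASN past the threshold; ACACA (-0.27, SE 0.086 against 0.11 before, edgeR adjusted p = 0.131) and IGF1R (-0.30, SE 0.12 against 0.14, edgeR adjusted p = 0.227) missed it. CAMK2N1 was the single riser among 15 androgen-repressed genes (median 0.38, camera adjusted p = 0.141). The MYC targets NDUFAF4 (0.89) and NPM1 (0.58, but -0.0038 on log2(TPM + 1)) rose, with a list median of 0.12 (camera adjusted p = 0.133). NPM1 was at 0.33 with the length trend removed (SE 0.099 against 0.10 before, edgeR adjusted p = 0.121) and missed the threshold without control replicate 1 or 2, and NDUFAF4 missed it without control replicate 1.

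The VCaP comparison asked what lowering FAM3B did in tumours of castrated mice. FAM3B was at 27.9 ± 1.61 CPM (SD, n = 4) in shControl and 10.7 ± 4.92 CPM (SD, n = 4) in shFAM3B tumours, lower in 4 of 4. Its log2 fold change of -1.39 (SE 0.27) missed the threshold over all genes (edgeR adjusted p = 0.0756) and passed it with DESeq2 (adjusted p = 0.000168, the lowest over the alternatives, the highest being 0.217). The shControl tumours held 26.4, 27.5, 30.2 and 27.5 CPM, and the shFAM3B tumours 6.61, 6.20, 15.01 and 14.8 CPM. Neuroendocrine, inflammatory and mesenchymal genes were higher as lists, and ribosomal and mitochondrial genes lower (limma camera). With an estimated correlation these lists had an adjusted p from 0.308 to 0.704 and 0 lists passed. Of the 35 splits of the tumours into 4 and 4, 16, the real one included, put as many lists past the threshold.

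Of 15811 genes tested in VCaP, 16 rose and 0 fell (edgeR); at an unadjusted p under 0.05 there were 1248 higher and 1186 lower, DESeq2 called 418 and 142, and limma-voom called 0 and 0. The largest rises were RBM24, an RNA-binding splicing regulator (0.247 ± 0.120 to 3.26 ± 1.503 CPM, log2 fold change 3.69, SE 0.46) and the potassium channel KCNC2 (3.13, SE 0.44). Next were the small GTPase RHOJ (3.33 ± 0.27 to 20.04 ± 10.3 CPM, 2.59, SE 0.34) and CADPS, which primes secretory vesicles (2.35, SE 0.36). They were followed by SOGA3 (2.23), the secreted hormone STC1 (1.28), the sphingomyelinase SMPD3 (1.27), XKR7 (1.27), the immediate early transcription factor EGR1 (1.19), the presynaptic scaffold BSN (1.14), the transcription factor MAF (1.11) and the secretory granule protein SCG3 (0.96). The remaining calls were the neuronal calcium channel CACNA1B (0.94), the growth factor receptor EGFR (31.9 ± 2.70 to 60.4 ± 9.83 CPM, 0.92), CECR6 (0.85) and LIMS1, an adhesion adaptor with near-identical copies (0.71). In the same libraries, of 10 bins by length, the shortest had a median of -0.17 and the longest 0.14. The 16 calls had a median length of 4079 bases against 2220 for all tested. With the length trend removed 0 genes passed (edgeR adjusted p from 0.0535 to 0.111 for the 16, against 0.0325 to 0.0479 without the correction). The folds lay from 0.63 to 3.74 with the correction and from 0.71 to 3.69 without it: RBM24 went from 3.69 (SE 0.46) to 3.74 (SE 0.47), SCG3 from 0.96 (SE 0.14) to 0.92 (SE 0.13) and EGFR from 0.92 (SE 0.13) to 0.73 (SE 0.11). The lost threshold does not show length as the cause of these rises. The calls also ended without shControl replicates 1, 2 or 4 (0 genes each) and nearly so without shFAM3B replicate 4 (1 gene, not among the 16). Leaving out the others gave more: 34 higher and 2 lower without shControl replicate 3, 42 and 2 without shFAM3B replicate 1, 31 and 4 without shFAM3B replicate 2, and 85 and 17 without shFAM3B replicate 3.

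**Figure D4:**
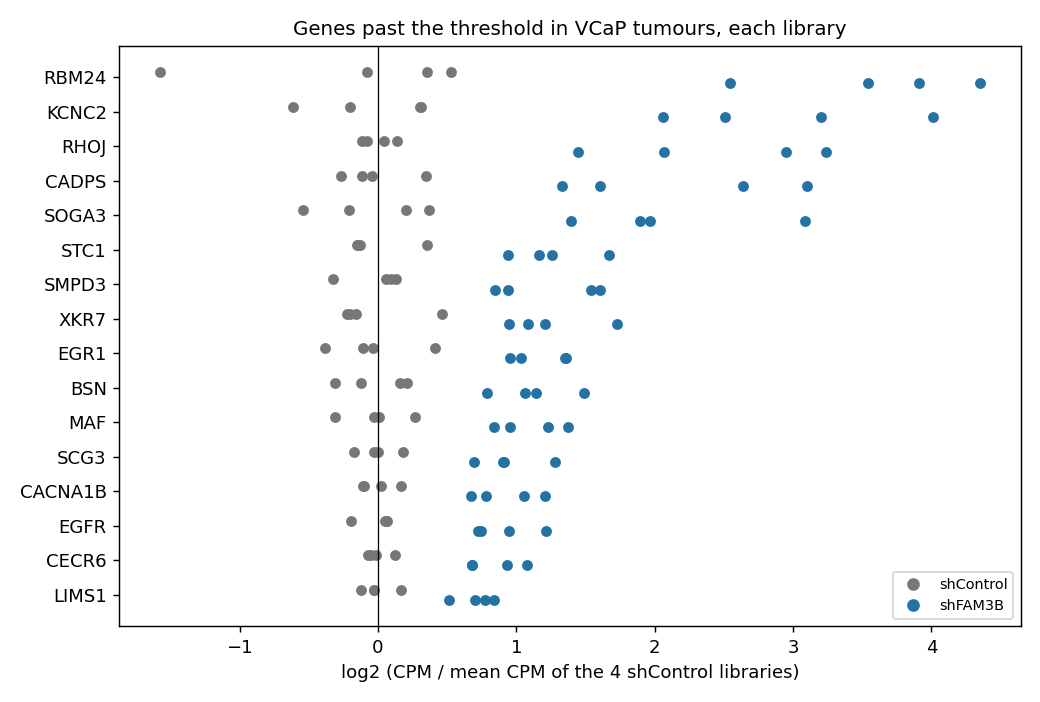
Log2 ratio of each VCaP library's CPM to the mean of the 4 shControl libraries (x axis), for the 16 genes past the threshold; grey dots are shControl and blue dots shFAM3B tumours. In each of these genes every shFAM3B tumour lies above every shControl tumour.

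Neuroendocrine markers had the largest list median in VCaP. Of 20 tested, SCG3 rose and 19 did not pass; adjusted over the list alone, 10 rose, and 15 had a positive fold change. The median was 0.56 (limma camera adjusted p = 0.000359; adjusted p = 0.308 with an estimated correlation). On log2(TPM + 1) it was 0.35 (camera adjusted p = 0.0266), where the median of all genes was 0.15, against -0.022 by counts. SRRM4, a neural splicing factor, was at 2.72 (edgeR adjusted p = 0.0699) and the granule protein CHGB at 1.19 (edgeR adjusted p = 0.0931). Of 19 NF-kB and inflammatory genes 0 passed (edgeR) and 7 rose adjusted over the list alone. The list's median was 0.19 (limma camera adjusted p = 0.000699, or 0.308 with an estimated correlation). The chemokine CXCL8 was at 2.34 and CCL2 at 1.10. CXCL8 was scarce, so its fold is uncertain. It held 0.468 CPM in shControl replicate 2 and 0.0787 to 0.124 CPM in the other shControl tumours. Of 16 mesenchymal genes 0 passed, 6 rose and 1 fell adjusted over the list alone, and the median was 0.27 (limma camera adjusted p = 0.00213; adjusted p = 0.308 with an estimated correlation), with the integrin ITGA5 at 0.95 and the matrix protein TNC at 1.48. Fibroblast markers, whose cells are murine in a xenograft, were higher beside them: a median of 0.27 over 18 genes, 0 passing and 2 adjusted over the list alone (limma camera adjusted p = 0.0229; adjusted p = 0.704 with an estimated correlation), with FBN1 at 1.13 and FSTL1 at 0.65. That call ended without shControl replicate 3 (0.19, adjusted p = 0.104), without shFAM3B replicate 3 (0.12, adjusted p = 0.416) and with the length correction (0.19, adjusted p = 0.0781).

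Androgen-induced genes were higher in shFAM3B tumours by less. Of 99 androgen response genes MAF rose and 98 did not pass (9 rose adjusted over the list alone), with a median of 0.12 (limma camera adjusted p = 0.00156; adjusted p = 0.382 with an estimated correlation). Of 29 canonical androgen-induced genes 0 passed (edgeR); adjusted over the list alone 7 rose and 1 fell, and the median was 0.14 (limma camera adjusted p = 0.0248; adjusted p = 0.308 with an estimated correlation). FKBP5 was at 0.88 (edgeR adjusted p = 0.0776), the ion channel TRPM8 at 1.01 (edgeR adjusted p = 0.0826), TMPRSS2 at 0.82 (edgeR adjusted p = 0.0887) and KLK3 at -0.27 (edgeR adjusted p = 0.576). In this list the call ended without shControl replicate 2 (0.17, adjusted p = 0.111) or 4 (0.21, adjusted p = 0.0524) and with the length correction (0.16, adjusted p = 0.0781). It also ended without a filter (adjusted p = 0.0519), by library size alone (adjusted p = 0.0835), against protein-coding genes (adjusted p = 0.0502) or on log2(TPM + 1) (adjusted p = 0.0713).

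Ribosomal, respiratory and mitochondrial transcripts were lower as lists with shFAM3B, though not in every tumour. The 49 ribosomal protein genes had a median of -0.22, with 49 below 0 and 0 passing (edgeR; limma camera adjusted p = 2.8e-08; adjusted p = 0.704 with an estimated correlation). The 51 respiratory chain genes had a median of -0.18, with 50 below 0 and 0 passing (limma camera adjusted p = 3.9e-06; adjusted p = 0.704 with an estimated correlation). Relative to the shControl mean, the ribosomal medians of the 4 shFAM3B tumours were -0.33, 0.063, -0.14 and -0.51, and the respiratory chain medians -0.31, 0.095, -0.23 and -0.32. In both lists replicate 2 lay above 3 of the 4 shControl tumours. On log2(TPM + 1), which put the median of all VCaP genes at 0.15 (-0.022 by counts), the respiratory chain median was 0.029 (camera adjusted p = 0.00172) and the ribosomal median -0.019, both below that of all genes. Without shFAM3B replicate 4 the ribosomal median was -0.12, and without shFAM3B replicate 2 the respiratory chain median was -0.27. In both lists 0 genes passed adjusted over the list alone. With the length trend removed their medians were -0.057 (camera adjusted p = 0.0939) and -0.050 (camera adjusted p = 0.0870). The 13 mitochondrially encoded genes had a median of -0.32 (limma camera adjusted p = 0.000359; adjusted p = 0.569 with an estimated correlation), with 4 lower adjusted over the list alone, MT-CYB at -0.44 and MT-CO3 at -0.42. The mitochondrial share of counts was 22.8%, 25.7%, 27.8% and 24.2% in shControl and 22.6%, 21.7%, 22.7% and 20.3% in shFAM3B tumours. Amino acid response genes had a median of -0.23 over 28 genes (limma camera adjusted p = 0.0213, or 0.704 with an estimated correlation). Adjusted over the list alone, 1 was higher and 1 lower. NUPR1 was at -0.54 and the serine synthesis enzyme PHGDH at -0.60, so the higher member is not among the genes named. The list median was -0.07 without shControl replicate 3 (camera adjusted p = 0.356) and -0.21 without shFAM3B replicate 3 (camera adjusted p = 0.140). Hypoxia and glycolysis genes had a median of 0.15 over 36 genes, 0 of them passing adjusted over the list alone (limma camera adjusted p = 0.0148; adjusted p = 0.704 with an estimated correlation), with the glucose transporter SLC2A3 at 1.15 and the demethylase KDM3A at 0.56. It was lost without shControl replicate 1 (0.17, adjusted p = 0.0972) or 4 (0.14, adjusted p = 0.0999) and without shFAM3B replicate 2 (0.04, adjusted p = 0.240).

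**Figure D5:**
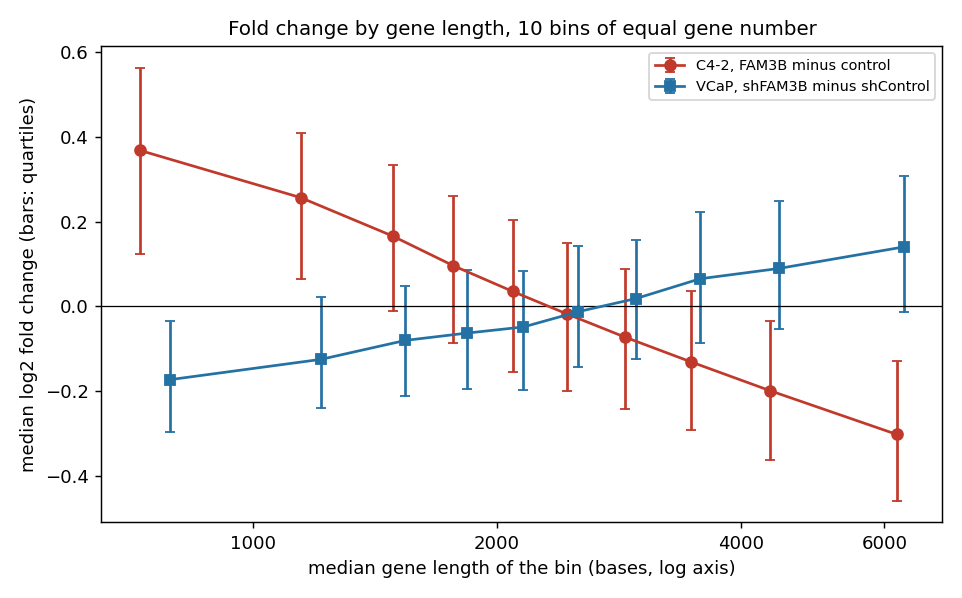
Median log2 fold change (y axis, bars are quartiles) in 10 bins of gene length (log x axis, bases), for C4-2 (FAM3B minus control) and VCaP (shFAM3B minus shControl). Medians run from 0.37 to -0.30 with increasing length in C4-2 and from -0.17 to 0.14 in VCaP.

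A gene that depends on FAM3B in the same way in both lines would move in opposite directions when FAM3B is raised in C4-2 and lowered in VCaP. Whether cultured C4-2 cells and VCaP tumours share such a dependence was not tested. Of 13579 genes tested in both, 0 passed in both (edgeR; DESeq2 39 opposite and 2 the same way; limma-voom 0). At an unadjusted p under 0.05 in both, 450 genes moved in opposite directions and 72 in the same direction, 86.2% opposite, against about 245 of each from independent lists (Fisher's exact test of the signs, two-sided, p = 2.7e-67, over genes, which are not independent replicates). With the length trend removed these numbers were 228 and 130, 63.7% opposite; without FAM3B replicate 1 of C4-2 they were 488 and 200, 70.9% opposite. Of the VCaP libraries left out in turn, shControl replicate 3 gave the lowest unadjusted share (365 and 111, 76.7% opposite). The highest came without shFAM3B replicate 2 (570 and 47, 92.4% opposite). C4-2 FAM3B replicate 1 and VCaP shControl replicate 3 had the most negative slopes of expression on log2 gene length in their experiments (-0.19 each). Leaving out a VCaP library put the adjusted count of opposite genes at 0 to 4, the highest without shFAM3B replicate 3. The test of the difference between the effects called 0 of 18799 genes (edgeR; 1904 at an unadjusted p under 0.05; 14 without shControl replicate 3), so a gene or list that passed in only 1 line is not shown to differ. Both effects are oriented as more FAM3B minus less FAM3B in this test, and for FAM3B the difference was 3.72 (edgeR adjusted p = 0.0681). Of the lists, ribosomal proteins differed, with a C4-2 effect 0.33 above the VCaP effect (limma camera adjusted p = 2.5e-05; adjusted p = 0.861 with an estimated correlation), which did not hold without FAM3B replicate 1 of C4-2 (0.13, adjusted p = 0.330) or with the length correction (0.13, adjusted p = 0.0568). For canonical androgen-induced genes the difference was -0.12 (camera adjusted p = 0.231).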

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

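The gene-length and GC corrections, the directions of genes after the length correction and the matched random lists were chosen after seeing the data. Among 112 groups of 4 VCaP libraries checked for a library standing apart (gap to the nearest other library over the whole range above 0.829), 6 had one, and chance gives about 1 in 20.

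STC1 was at 11.9 CPM in shControl replicate 2 against 8.33 to 8.46 CPM in the other 3. XKR7 was at 27.3 CPM in shControl replicate 3 against 16.9 to 17.7 CPM. The ERG-linked potassium channel gene KCNH8 was at 12.9 CPM in shControl replicate 3 against 22.5 to 23.9 CPM. CXCL8 was at 0.468 CPM in shControl replicate 2 against 0.0787 to 0.124 CPM. EGFR was at 27.8 CPM in shControl replicate 3 against 33.1 to 33.4 CPM. The fibroblast list had a median deviation from the mean of the 8 tumours of -0.36 in shControl replicate 3 against -0.02 to 0.01 in the other shControl tumours. The XKR7, KCNH8, EGFR and fibroblast flags all fell on shControl replicate 3. That tumour also had the most negative slope of expression on log2 gene length (-0.19, against -0.039 to 0.0092 in the other shControl tumours). Its mitochondrial share of counts was the highest (27.8%), and neither value met the criterion above.

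Ribosomal proteins differed between the lines by the test of the difference, the C4-2 effect (median 0.53) lying 0.33 above the VCaP effect (limma camera adjusted p = 2.5e-05, or 0.861 with an estimated correlation). Both effects are oriented here as more FAM3B minus less FAM3B. The VCaP median was -0.22 for shFAM3B minus shControl, so in both lines the list was higher with more FAM3B, and by more in C4-2. The difference was 0.13 without FAM3B replicate 1 of C4-2 (adjusted p = 0.330) and 0.13 with the length correction (adjusted p = 0.0568). Of the genes past an unadjusted p of 0.05 in both lines, 86.2% moved in opposite directions. The tables argue against GC content as the cause of the C4-2 rise (0.54 after the GC correction). The C4-2 median lay above 0.46, the upper percentile bound for the medians of 10000 random lists matched on length and abundance. That cannot decide whether length and abundance are its whole cause. The matched genes were longer (757 against 695 bases) and less abundant. They were also drawn independently, while the ribosomal genes had an estimated correlation of 0.93. Gene length could account for much of both patterns: with each library's length trend removed the ribosomal median was 0.18 (camera adjusted p = 9.2e-06) and the share of opposite directions 63.7%, against 50.4% from independent lists. Both values lie between the bounds set for and against gene length, so gene length and a FAM3B effect cannot be told apart here. A difference between the FAM3B libraries of C4-2 stays open too, with ribosomal medians of 0.69 and 0.35. FAM3B replicate 1, with the larger median, held less FAM3B than replicate 2. Its slope of expression on log2 gene length was steeper (-0.19 against -0.014). In VCaP, shFAM3B replicate 2 held the least FAM3B, yet its ribosomal median was not below the shControl mean. Its length slope was -0.029, against 0.048 to 0.10 in the other shFAM3B tumours. In these libraries the list followed the length slope more closely than the FAM3B level, but they are too few to decide.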

How the results depend on the processing

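The gene-length and GC corrections were chosen after seeing the data; all other alternatives were planned. Over the named genes and other lists under these alternatives, 2862 values were counted as the same, 445 lost their call and 112 gained it. Another 13 reversed direction with a call in the main test or the alternative. A change of sign without a call in either counted as the same. DESeq2 list medians, which had no list test, counted as the same when within the replicate SD of the main value. In C4-2, FAM3B passed under every alternative tried (4.07 to 5.45). With an estimated correlation or with fry, 0 lists passed in either line: the androgen response list had an adjusted p of 0.86 and 0.339 in C4-2 (-0.21) and 0.382 and 0.125 in VCaP (0.12). Where no reason is given below, the cause was not tested. At these library numbers, depths and spreads, simulated 1.5-fold changes were recovered in 25.4% (C4-2) and 26.9% (VCaP) of cases. The simulated genes varied independently, so these rates leave out the trends shared within the real libraries.

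C4-2 calls were 192 higher and 498 lower by library size alone, 664 and 491 with DESeq2, 930 and 790 without a filter, 13 and 15 in a single fit of 12 libraries, 4 and 0 on log2(TPM + 1), 8 and 4 on log2(TPM + 0.1), 229 in total with the length correction, 113 of them lower and 1.2e+02 higher (171 shared with the 586 calls without it), and 1188 and 1028 with the GC correction. Leaving out a library gave 73 to 2658 higher and 65 to 2619 lower; the high numbers arise without a FAM3B library, when the spread comes from the control pair alone, whose lone partner is assumed to vary alike. Lists past the threshold numbered 5 on log2(TPM + 0.1) and 4 to 9 with a library left out. The androgen response list was -0.049 with the length correction and -0.27 to -0.16 with a library left out.

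VCaP calls were 52 higher by library size alone, 418 higher and 142 lower with DESeq2, 0 higher with limma-voom, 276 and 63 without a filter, 140 and 30 in a single fit of 12 libraries, 6 higher on log2(TPM + 1), 28 higher on log2(TPM + 0.1), 0 higher with the length correction and 37 higher with the GC correction. Leaving out a library gave 0 to 85 higher and 0 to 17 lower. Lists past the threshold numbered 7 with the length correction and 9 to 15 with a library left out. FAM3B passed with DESeq2 (-1.37), without a filter (-1.39) and in a single fit of 12 libraries (-1.37), and was -1.60 to -1.19 with a library left out, past the threshold in 1 case, without shFAM3B replicate 3 (-1.60). Genes called in both lines in opposite directions numbered 450 at unadjusted p, 228 at unadjusted p with the length correction, 3 by library size alone, 39 with DESeq2, 32 without a filter, 1 in a single fit and 0 to 4 with a library left out. Genes whose effect differed between the lines numbered 2 with the length correction and 0 to 14 with a library left out.

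The median of all genes was 0.0054 in C4-2 and -0.022 in VCaP by counts, and on the TPM scalings -0.20 and -0.24 in C4-2 and 0.15 and 0.21 in VCaP. HSPA8 (0.41 by counts) and NPM1 (0.58) moved by more than that. The C4-2 values given next lie above the median of all genes on the same scaling and the VCaP values below it, and the cause of the reversals was not tested. On log2(TPM + 1) and log2(TPM + 0.1), C4-2 HSPA8 was -0.10 and -0.10, NPM1 -0.0038 and -0.0038, the DNA replication list -0.082 and -0.083, the mitosis list -0.034 and -0.036, and the chaperone list -0.029 and -0.029. The VCaP respiratory chain list was 0.029 and 0.029, and the VCaP steroid metabolism list, -0.12 by counts, was 0.019 on log2(TPM + 1).

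Same-numbered replicates did not all deviate together in VCaP (correlations 0.24, 0.08, 0.0036 and -0.11), so the numbers were not taken to pair the samples. In C4-2 the correlation was 0.099 for the same number and -0.099 for the other. With 2 libraries per group these values mirror each other, so pairing there cannot be judged from them. With the replicate number as a block, C4-2 calls were 1222 higher and 1169 lower and VCaP calls 91 and 19, FAM3B in VCaP passed (-1.50), and 16 genes were called in both lines in opposite directions. In VCaP, shControl replicates 2, 3 and 4 each correlated better with a shFAM3B tumour of another number (0.11, 0.069 and 0.15) than with that of their own.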

Other observations

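The gene-length and GC corrections used here were chosen after seeing the data; leaving out libraries and the other splits of the samples were planned. Relatives of FAM3B were measured in both lines. FAM3A was at 0.11 in C4-2 and -0.19 in VCaP, and FAM3C at 0.22 and -0.19, with 0 of these passing (edgeR adjusted p from 0.301 to 0.672). FAM3C2, a pseudogene that shares sequence with FAM3C and is therefore uncertain, held 279 and 260 counts in C4-2 controls and 108 and 0 with FAM3B (edgeR adjusted p = 0.141), and it was at 1.02 in VCaP (edgeR adjusted p = 0.0805). Of the genes beside FAM3B on chromosome 21, TMPRSS2 fell in C4-2 (-0.53), a call that ended without control replicate 1 or 2; in VCaP the 6 tested neighbours had a median of 0.24 (camera adjusted p = 0.178).

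Other lists were tested and did not pass. In C4-2, antigen presentation genes had a median of 0.25 (camera adjusted p = 0.0729) and FOXO and PI3K-AKT feedback genes -0.14 (camera adjusted p = 0.0918). The muscle list had TTN, the giant sarcomere protein with one of the longest transcripts, at -1.22 (SE 0.21, edgeR adjusted p = 0.0246), and at -0.85 with the length correction (SE 0.20, edgeR adjusted p = 0.0649). In VCaP, ERG-linked genes had a median of 0.14 and interferon-stimulated genes 0.13 (camera adjusted p = 0.0611 each), and KCNH8 was at 1.56 (edgeR adjusted p = 0.0545). Replication-dependent histones, which lack poly(A) tails, had a median of -0.49 (camera adjusted p = 0.0611), and immediate early genes 0.13 (camera adjusted p = 0.0775), EGR1 among them. Endothelial (0.13), leukocyte (0.02), adipocyte (0.15) and muscle (-0.25) markers did not pass in VCaP (camera adjusted p from 0.595 to 0.971).

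Canonical androgen-induced genes were lower in C4-2 with FAM3B, with a median of -0.36. Removing each library's length trend left -0.30 (camera adjusted p = 9.2e-06) and removing its GC trend left -0.40, which argues against either trend as the whole cause, and leaving out each library gave -0.45 to -0.29. A weaker response to androgen with FAM3B may contribute, as a hypothesis drawn from these same data, and no test here could settle it. Open beside it are a difference between the inducible and control cells other than FAM3B, which was not tested, and the spread of 2 libraries per group. With an estimated correlation the adjusted p was 0.86, and the wider androgen response list was at -0.049 with the length correction.

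Neuroendocrine markers were higher in shFAM3B tumours, with a median of 0.56. The tables argue against gene length as the whole cause (0.52 after the correction, camera adjusted p = 0.00108) and against a single tumour (lowest median 0.45 with 1 library left out, highest camera adjusted p = 0.00179). A difference with FAM3B stays open, as a hypothesis, and so does one in tumour composition that could move whole lists together, since fibroblast markers were higher too (0.27). Camera gave this list an adjusted p = 0.308 with an estimated correlation. In C4-2, 8 of its members were tested, with a median of 0.094 with FAM3B (camera adjusted p = 0.684). Raising FAM3B there thus showed no fall of the list.

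Of the 35 splits of the 8 tumours into 4 and 4, 1, the real one, called 16 genes or more. The highest other called 2. No smaller share than 1 of 35 is possible, so chance is less likely for that count but not excluded. The count was 0 with limma-voom, with the length correction, and without shControl replicate 1, 2 or 4. For the 11 lists past the threshold chance cannot be excluded: 16 of the 35 splits gave as many, and the highest other gave 18.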
